A study of Homo sapiens with 3 samples.

How the data were processed

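Total RNA from TOV21G cells was extracted with Trizol, cleaned and treated with DNase, made into libraries with a ScriptSeq complete Gold kit and sequenced as 75 bp reads on a NextSeq 500, per the labels' protocols. The authors deposited a table of estimated counts per Ensembl gene as whole numbers, with 1 column for each of the 3 libraries. Per the submitters' processing notes, RSEM 1.2.3, edgeR and the hg19 genome build were used, without a statement of which step each did. RSEM divides reads that fit several genes between them by a model, so an estimated count of a gene with a near-identical copy depends on that division. Whether the counting used strand is not given in the sources used here. The estimated counts were already whole, and rounding changed none of them.

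The table held 57736 gene rows, 34038 of them without a count in any library. Gene IDs were matched to GENCODE release 29, and 51959 were found there; 31126 were named by the symbol in the table, 20833 by the reference symbol where the table's symbol was neither its current nor an older name, and 5777 that were not in the reference kept the table's name. The hg19 annotation was not used here, and the table gives no coordinates. GENCODE 29 (GRCh38) served for names, gene types, the GC content and length of each gene's longest transcript, the share of 75-base sequences that a gene's transcripts have in common with other genes, and the position of the hairpin stems. A gene was said to possibly share reads where at least 20% of these sequences were shared, where its symbol stood in more than 1 row, where its name joined those of neighbouring genes (a read-through), or where it had no sequence in the reference. GC content was known for 97.2% of the genes tested.

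Libraries were grouped by the genotype in the labels, into WT (n = 1) and HDAC2 knockdown (n = 2, 1 library per hairpin). The total counts were 10138479, 11398791 and 11225492 for WT, shRNA 1 and shRNA 2, and 3 counts, the limit that a count of 0 allows, equalled 0.296, 0.263 and 0.267 CPM. Such limits cover counting error only. Nothing in the labels says that the knockdown libraries are more than 1 culture per hairpin.

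The main test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR 4.0.16, R 4.3.3), with TMM scaling and filterByExpr at its defaults, and an adjusted p below 0.05 as threshold. The 3 libraries left 1 residual degree of freedom, to which the fit added a prior of 18.9 degrees of freedom learned over all genes. Standard errors (SE) of log2 changes were derived from the estimate and its F statistic. Changes of single hairpins were taken from log2 CPM with a prior count of 2, and have no test. In a simulation of this comparison on 14524 genes, 200 genes were changed, and the test recovered 13.4% of those changed 1.5-fold, 44.8% of those changed 2-fold and 90.9% of those changed 4-fold, with 3 unchanged genes called. The depth and the lone WT library therefore leave most changes near 1.5-fold undetected.

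Before the data were examined, 33 gene lists were fixed, and 31 had at least 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists, and again with an estimated correlation. The second test ran on 1 residual degree of freedom. Its adjusted p by camera was at least 0.86 for every list, and at least 0.80 with a GC trend removed. It therefore cannot tell a firm list call from a weak one. The preset correlation treats the members of a list as nearly independent, so its p-values are too small where members move together. Members past the test were counted over all genes and adjusted over the list alone. List medians were compared with 10000 random lists matched on mean expression, whose genes need not move together. The list of mitochondrially encoded genes had 0 of its 13 members in the table used and was not analysed here, and of the leukocyte list 2 members were tested. Camera and the GC correction were also tested on simulated data of 14524 genes, where 0 genes were called without change and 17 with the observed GC trend alone, and 0 after correction.

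Genes to name were also fixed before the data were examined. They were HDAC2, HDAC1, HDAC3, HDAC8, ARID1A, EZH2, PIK3IP1 and CDKN1A, and then 12 rising and 12 falling genes. The latter passed the test, changed at least 2-fold with the same sign by both hairpins and had a mean count of at least 50 in the higher group, ranked by the smaller of the hairpins' changes and leaving out unnamed clones. The rule further took up to 2 rising and 2 falling members of each list, and the 3 genes highest and the 3 lowest in shRNA 2 against shRNA 1. Genes outside the rule are marked as chosen after their values were seen.

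The alternatives tried were DESeq2 size factors (DESeq2 1.42.0), library size alone and upper quartile scaling, no filter and a mean count of at least 50, DESeq2's Wald test, edgeR's likelihood ratio test and limma-voom, adjusted p thresholds of 0.01 and 0.1, leaving out mitochondrial copies, histones and small RNAs, other fold thresholds and prior counts, and leaving out each hairpin. Further alternatives were chosen after seeing the data: removing a smooth trend of each knockdown library on GC content, summing genes that share at least 50% of their 75-base sequences, and counting only genes with no near-identical copy. Plots were drawn with matplotlib 3.10.9.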

Results

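RNA levels were measured by sequencing of total RNA from TOV21G, a human cell line from an ovarian clear cell carcinoma with a mutated ARID1A gene. ARID1A encodes a subunit of the SWI/SNF chromatin remodelling complex. The table held 3 libraries: 1 of wild-type cells (WT) and 2 of cells in which HDAC2, a class I histone deacetylase, was depleted by a lentiviral short hairpin RNA. Each knockdown library came from a different hairpin, called shRNA 1 and shRNA 2. The libraries held 10138479 counts (WT), 11398791 counts (shRNA 1) and 11225492 counts (shRNA 2), and 14524 genes passed the filter on low counts. The labels do not say whether the WT cells received a control virus, so knockdown and transduction were not separated by this design. The WT group had no replicate. The p-values below measure the spread between the 2 hairpin libraries, and the lone WT library is assumed to vary as they do.

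Over their full 21 bases, the stems of both hairpins matched HDAC2 alone among annotated transcripts with up to 2 mismatches. Matches of a shorter part of a stem, or of its other strand, were not searched. This search therefore does not show that the hairpins act on HDAC2 alone. The hairpin listed first in the labels carries the stem CAGTCTCACCAATTTCAGAAA, which matched the minus strand of chromosome 6 from 113941031 to 113941051 (GRCh38), in the 3' UTR of HDAC2, within the last exon of its protein-coding transcripts. The hairpin listed second carries GCAAATACTATGCTGTCAATT, which matched chromosome 6 from 113949221 to 113949241 on the same strand, in the coding sequence, within exon 8 of 15 of one HDAC2 transcript and exon 7 of 14 of the other protein-coding ones. With 3 mismatches, the first stem also matched 3 other genes and the second stem 1. Of those 4, SBNO1 and VPS52 had enough counts to be tested, and neither passed the test, at log2 changes of 0.48 ± 0.19 (SE) and −0.30 ± 0.20 (SE). Which of the stems is shRNA 1 is not stated in the labels, so no library was assigned to a stem.

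HDAC2 RNA (ENSG00000196591) was lower in both knockdown libraries, which had normalised levels (CPM) of 33.4 and 51.6 with shRNA 1 and shRNA 2 against 105 in WT. These levels were 31.7% and 48.9% of WT, and the knockdown mean was 42.5 ± 12.8 CPM (SD, n = 2). The log2 change was −1.31 ± 0.20 (SE), with an adjusted p of 4.82e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 326 CPM to 289% ± 78.6 of the WT level (SD, n = 2), a log2 change of 1.53 ± 0.20 (SE; adjusted p = 1.67e-04 by the same test). PIK3IP1, an inhibitor of phosphoinositide 3-kinase (PI3K), had 25 counts in WT and 67 and 52 in the knockdown libraries, a log2 change of 1.05 ± 0.41 (SE) that did not pass over all genes (adjusted p = 0.119 by the same test). Its adjusted p was 0.0355 when adjusted over the list alone, the 8 genes fixed in advance.

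The related deacetylases did not pass the test over all genes. The log2 change was −0.27 ± 0.17 (SE) for HDAC1, −0.54 ± 0.17 (SE) for HDAC3 and −0.28 ± 0.22 (SE) for HDAC8, which shares 50.5% of its read-length sequences with other genes and is uncertain. ARID1A itself differed by −0.36 ± 0.17 (SE), and EZH2, the methyltransferase of Polycomb repressive complex 2, by −0.27 ± 0.18 (SE). With a trend in transcript GC content removed, HDAC3 and ARID1A differed less, by −0.39 and −0.12. HDAC1 then differed by −0.26, and HDAC8 and EZH2 differed more, by −0.47 and −0.41. The 8 genes fixed in advance include HDAC2, the knockdown target, whose low p eases the adjustment over that list. HDAC3 passed when adjusted over the list alone (adjusted p = 0.0113, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

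**Figure D1:**
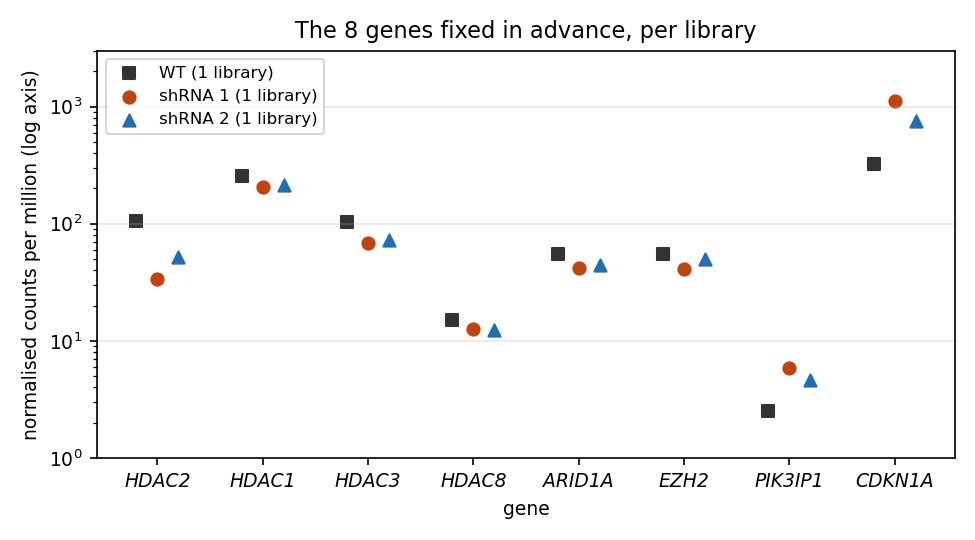
Normalised level (CPM) on a log axis for the 8 genes fixed in advance, with 1 point per library (WT, shRNA 1, shRNA 2) and no error bars because each point is a single library. HDAC2 lies at 105 in WT against 33.4 and 51.6 in the knockdown libraries, and CDKN1A at 326 against 1121 and 759.

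The comparison of knockdown with WT asked which genes change when HDAC2 is depleted in ARID1A-mutated cells. Among the named genes without a near-identical copy, the nuclear long noncoding RNA MALAT1 rose 3.65-fold, from 207 to 754 ± 26.2 CPM (SD, n = 2). TRIM22, an interferon-inducible ubiquitin ligase, rose 3.77-fold, and CPA4, a metallocarboxypeptidase, rose 5.17-fold. CENPM, a centromere protein, fell to 0.309 of WT, TK1, the thymidine kinase of the nucleotide salvage pathway, to 0.357, and GLI1, a transcription factor of Hedgehog signalling, to 0.303. NRGN, a calmodulin-binding protein, fell by 1.74 on the log2 scale, and KCNH3, a potassium channel, by 1.52. The calls of GLI1 and KCNH3 were lost with a trend in transcript GC content removed (adjusted p = 0.0687 and 0.0900, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Their log2 changes then were −1.46 and −1.15, from −1.72 and −1.52.

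In all, 1121 of 14524 genes changed, 575 upwards and 546 downwards (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 3420 passed at an unadjusted p below 0.05. Of the 575, 574 were above WT in both hairpin libraries, and all 546 were below it in both. With a trend in the GC content of the transcripts removed, an alternative chosen after seeing the data, 492 genes passed, 202 upwards and 290 downwards, and 429 of them were among the 1121. The fit with the GC trend removed had a prior of 11.5 degrees of freedom against 18.9, so a lost call need not mean a smaller change. In it HDAC2's log2 change grew to −1.59, yet its adjusted p rose to 0.00146 by the same test. With no filter on low counts, 0 genes passed by the same test, although 2486 had an unadjusted p below 0.05. On the filtered table, 306 passed DESeq2's Wald test.

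The largest named changes lay in genes that may share reads with others, and these are uncertain. Of the 12 rising genes taken by the rule, 9 may share reads with a copy or an overlapping gene. These include GRAMD4P3, which has no sequence in the reference, so its sharing was not measured. CTAGE4 (ENSG00000256178), GRAMD4P3, the read-through UBE2F-SCLY and the pseudogene RPL9P7 had 0 counts in WT and were at least 25.0-fold, 15-fold, 18.1-fold and 23.3-fold higher in knockdown cells, against a floor of 3 counts. These limits are for the mean of 2 unequal libraries. With shRNA 1 and shRNA 2 the counts were 117 and 55, 70 and 33, 84 and 40, and 128 and 32. ZNF709, LUZP6, PMS2P7 and the ribosomal protein gene RPL9 rose by 3.24, 2.46, 2.21 and 1.84 on the log2 scale, and BTF3L4P2 had 2 counts in WT and 95 and 148 in the knockdown libraries. Of the 12 falling genes, 6 may share reads. NDUFC2-KCTD14 had 93 counts in WT and 0 in both knockdown libraries, at least 70.8-fold lower against a floor of 3 counts over the group. FXYD6-FXYD2 fell by 2.19 on the log2 scale, CENPS-CORT by 2.28, TMSB4XP6 by 2.74 and PMS2L14 by 1.85, and RPS7P10, with 19.4% shared sequence, by 1.80. The call of TMSB4XP6 was lost with the GC trend removed, although its log2 change then was −2.88. Of other IDs with the same symbol, CTAGE4 (ENSG00000225932) had 32 counts in WT and 0 in both knockdown libraries, and PMS2L14 (ENSG00000188073) had 38, 116 and 141 counts in WT, shRNA 1 and shRNA 2. When genes that share sequence were summed, an alternative chosen after seeing the data, 5 of the 8 rising genes in summed groups lost their calls, namely CTAGE4, BTF3L4P2, UBE2F-SCLY, ZNF709 and LUZP6, and the sum that holds RPL9 and RPL9P7 changed by 1.12 on the log2 scale. Of the 5 falling genes in summed groups 3 lost their calls, TMSB4XP6 and PMS2L14 among them, and the changes of NDUFC2-KCTD14 and CENPS-CORT shrank to −0.60 and −0.63. GRAMD4P3 and FXYD6-FXYD2 were in no summed group, so this did not test them.

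Direct targets of the tumour suppressor p53 rose as a group. Of 31 tested members, 15 rose, 1 fell and 15 did not pass, and the median log2 change was 0.59. The counts adjusted over the list alone were 21 and 1. ZMAT3, an RNA-binding protein, rose 3.27-fold (log2 1.71 ± 0.20, SE), and TP53INP1, a stress-induced nuclear protein, rose 2.65-fold (log2 1.40 ± 0.20, SE). MDM2, the ubiquitin ligase that degrades p53 and a gene chosen after its values were seen, rose by 1.16 ± 0.17 (SE) on the log2 scale. TP53I11 was the member that fell, by 0.67 on the log2 scale, and 12 of the 15 rises but not this fall passed again with the GC trend removed. The list's adjusted p was 1.65e-13 by camera with a preset correlation. With an estimated correlation camera's adjusted p was 0.865. No list passed that test, which ran on 1 residual degree of freedom and cannot weigh this call.

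Genes of the cell division cycle fell together. Of 35 tested genes of the G2 phase and mitosis, 19 fell, 0 rose and 16 did not pass, with a median log2 change of −0.70, and all 35 were below WT in both hairpin libraries. KIF20A, a mitotic kinesin, fell to 0.416 of WT, and PLK1, a mitotic kinase, to 0.454. Of 40 genes of the G1/S transition and DNA replication, 28 fell, 1 rose and 11 did not pass, with a median of −0.76. E2F2, a transcription factor of S-phase entry, fell to 0.350 of WT and CDT1, a replication licensing factor, to 0.357, whereas CCND1, the gene of cyclin D1, rose 1.75-fold. Adjusted over the list alone, 29 of the G2 and mitosis genes fell, and 34 of the G1/S genes fell and 1 rose. The G2 and mitosis genes moved together between the hairpins, as 1 of the 35 was higher with shRNA 1 than with shRNA 2. Camera's preset correlation treats members as nearly independent, so its p-values are likely too small here. Camera's adjusted p was 6.07e-28 for each of the 2 lists with the preset correlation (adjusted p = 0.865 with an estimated correlation for both).

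Homologous recombination and mismatch repair genes also moved down. Of 26 tested, 8 fell and 0 rose, 8 also when adjusted over the list alone, with a median of −0.24 that was −0.46 with shRNA 1 and −0.11 with shRNA 2. XRCC3, a protein of homologous recombination, fell to 0.412 of WT and may share reads with another gene. The list's camera adjusted p was 0.00237 (adjusted p = 0.865 with an estimated correlation). Cyclin-dependent kinase inhibitors did not pass camera's test as a list (8 tested, adjusted p = 0.565), but their median, −0.53, lay at the 0.2 percentile of random lists. CDKN1A rose while CDKN2C (−1.22 ± 0.22, SE) and CDKN3 (−0.88 ± 0.21, SE) fell. Of these, 2 rose and 3 fell adjusted over the list alone.

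Death receptor genes and inhibitors of apoptosis were among the apoptosis genes that changed. Of 23 pro-apoptotic genes, 2 rose, the death receptor genes TNFRSF10B (1.64-fold) and FAS (log2 0.59 ± 0.17, SE), and 2 passed when adjusted over the list alone. Both are also members of the p53 target list, which shares 4 tested genes with this one, so their rises were counted there too. Of 11 anti-apoptotic genes, 3 rose, MCL1 at 1.62-fold, XIAP at 1.60-fold and BIRC2, named after its values were seen, at 0.64 on the log2 scale, and BIRC5, the gene of survivin, which also serves mitosis, fell to 0.535 of WT. The counts were again 3 and 1 adjusted over the list alone. Camera's adjusted p was 0.565 for the first list and 0.184 for the second, whose median of 0.48 lay at the 99.93 percentile of random lists and was 0.51 with shRNA 1 and 0.24 with shRNA 2. The calls of FAS, XIAP and BIRC2 were lost with the GC trend removed.

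**Figure D2:**
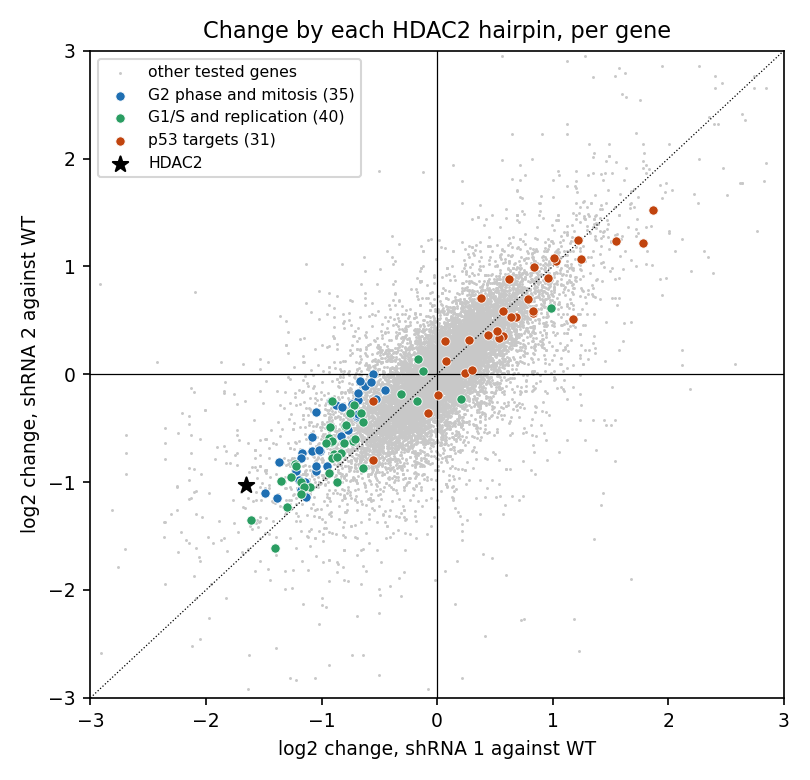
Log2 change against WT with shRNA 1 (x axis) and shRNA 2 (y axis) for each tested gene, with p53 targets, G2 and mitosis genes, G1/S and replication genes and HDAC2 marked; 107 genes lie outside the axes, which end at 3. Of the 35 G2 and mitosis genes, 35 lie below 0 on both axes, and 27 of 31 p53 targets lie above 0 on both.

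Few genes for chromatin regulators passed the test. Of 18 deacetylases and sirtuins, HDAC2 alone fell (3 adjusted over the list alone), and the list's camera adjusted p was 0.184. Of 34 other subunits of the NuRD, SIN3 and CoREST complexes, which hold HDAC1 and HDAC2, RCOR2 fell, to 0.506 of WT (camera adjusted p = 0.353; 1 adjusted over the list alone). Of 9 Polycomb repressive complex 2 genes, the cofactor gene PHF19 fell, to 0.489 of WT, 1 also adjusted over the list alone. That list's median was 0.06 and its mean −0.03, and camera's direction was down (adjusted p = 0.676). Of 24 SWI/SNF subunits, ARID1B, the paralog of ARID1A, fell, to 0.681 of WT, and 0 passed adjusted over the list alone (median −0.25, at the 0.1 percentile of random lists, camera adjusted p = 0.0551). With the GC trend removed, ARID1B did not pass, and the SWI/SNF median was −0.13 (camera adjusted p = 0.142).

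Of 34 HOX genes, 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.327), with HOXC12 at −2.23 ± 0.90 (SE) and HOXC4, which may share reads, at −0.67 ± 0.24 (SE). Of 18 neuronal genes silenced by the repressor REST, BDNF, a neurotrophin, rose 1.72-fold (1 adjusted over the list alone, camera adjusted p = 0.676), a call lost with the GC trend removed. Of 23 replication-dependent histone genes, 3 rose, H2AC6 at 2.64-fold, H2BC4 at 1.72-fold and H1-2, named after its values were seen, at 0.85 on the log2 scale, and H1-4 fell to 0.389 of WT. Histone genes numbered 7 rising and 3 falling adjusted over the list alone. The list's median was 0.47, at the 99.8 percentile of random lists, and 0.28 and 0.48 with shRNA 1 and shRNA 2 (camera adjusted p = 0.311), and it passed, upwards, among genes with a mean count of at least 50 (adjusted p = 8.36e-04). That count filter, on the mean over the 3 libraries, left out H1-4, with 61, 27 and 27 counts in WT, shRNA 1 and shRNA 2. The list's pass with it therefore does not cover the member that fell. Of the 23 histone genes, 10 may share reads. The calls of H2BC4 and H1-4 were lost with the GC trend removed. Their log2 changes then were 0.79 and −1.08, from 0.78 and −1.36.

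Negative regulators of PI3K and AKT signalling included 3 rising genes of 20 tested. SESN3 and SESN1, stress-induced sestrins that restrain the growth kinase mTORC1, rose 2.58-fold and 2.08-fold, PIK3R3, which may share reads and was named after its values were seen, rose by 0.76 on the log2 scale, and DDIT4, which may share reads, fell to 0.672 of WT. SESN1 is also in the p53 target list, which shares 2 tested genes with this one. Adjusted over the list alone, 4 rose and 2 fell. The median was 0.14 and camera's adjusted p 0.0551, which became 0.00332 with the GC trend removed, and 0.804 with an estimated correlation as well. The call of DDIT4 was lost with the trend removed. Among genes with a mean count of at least 50, the list did not pass camera's test. Its mean log2 change over the 20 genes, 0.55, included INPP5D at 6.35, with 0 CPM in WT. Immediate early genes rose as a list (24 tested, 5 rose, 5 also adjusted over the list alone, median 0.24, with 0.38 for shRNA 1 and 0.16 for shRNA 2, camera adjusted p = 0.00788; adjusted p = 0.865 with an estimated correlation), with the stress factor ATF3 at 3.79-fold and KLF6 at 1.83-fold. The other 3 were CCN2, which the rule took from the YAP and TAZ targets, and the phosphatase genes DUSP4 and DUSP6. These phosphatase genes were named after their values were seen, and DUSP6 may share reads. With the GC trend removed, ATF3 and DUSP6 did not pass, although the log2 change of ATF3 was 1.91, from 1.92.

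Of 23 YAP and TAZ targets, CCN2, a matricellular growth factor, rose 2.11-fold and FOXF2 fell to 0.598 of WT (a call lost with the GC trend removed), 1 and 1 also adjusted over the list alone (camera adjusted p = 0.565). Interferon-stimulated genes included rising and falling members (28 tested, 2 rose, 3 fell, camera adjusted p = 0.743). TRIM22 and SAMD9 (2.47-fold) rose, and OAS3 fell to 0.519 of WT and IFITM1 to 0.604, while IFITM3 fell by 0.61 on the log2 scale and was named after its values were seen. IFITM1 and IFITM3 may share reads. With the GC trend removed, the calls of SAMD9 and all 3 falling genes were lost and that of TRIM22 was kept. The list had 3 rising and 4 falling genes adjusted over the list alone. Of 23 NF-kB target cytokines, 0 passed over all genes and 0 adjusted over the list alone (camera adjusted p = 0.565), with CXCL8 at 1.16 ± 0.52 (SE) and CX3CL1 at −0.95 ± 0.68 (SE).

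Among stress and metabolic lists, glycolytic and hypoxia-induced genes were lower as a list (32 tested, median −0.22, with −0.08 for shRNA 1 and −0.32 for shRNA 2, camera adjusted p = 0.0377). The 4 members that fell were the glycolytic enzyme genes PFKL (to 0.648 of WT), GAPDH (to 0.708; it may share reads), ENO1 and TPI1, the last 2 named after their values were seen, and 6 fell adjusted over the list alone. The list's call was lost with the GC trend removed (camera adjusted p = 0.293), as were all 4 of the members' calls. With an estimated correlation camera's adjusted p was 0.865, which cannot weigh the call on 1 residual degree of freedom. Of 30 genes of the unfolded protein and integrated stress response, ATF3 and the chaperone gene DNAJB9 (2.65-fold) rose, and the serine synthesis gene PHGDH (to 0.448 of WT) and SDF2L1 (to 0.508) fell. Adjusted over the list alone, 3 of them rose and 2 fell (camera adjusted p = 0.621), and the calls of ATF3 and SDF2L1 were lost with the GC trend removed. The log2 changes of ATF3 and SDF2L1 then were 1.91 and −0.60, from 1.92 and −0.98. Of 18 cytosolic heat shock genes, CRYAB rose 1.95-fold and HSPB1 fell to 0.621 of WT, 1 and 1 also adjusted over the list alone (camera adjusted p = 0.588), and the call of HSPB1 was lost with the GC trend removed.

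Of 24 cholesterol genes, 2 rose and 2 fell, among them the sterol desaturase gene SC5D, which rose 1.57-fold, and the sterol isomerase gene EBP, which fell to 0.641 of WT. All 4 calls were lost with the GC trend removed, and adjusted over the list alone 5 rose and 5 fell (camera adjusted p = 0.565). Of 24 lysosomal genes, the protease gene CTSL rose 1.74-fold and LAMP2 1.56-fold, 2 also adjusted over the list alone. Camera's adjusted p for lysosomal genes was 0.505, and 0.0251 with the GC trend removed, which also lost the call of LAMP2, and 0.804 with an estimated correlation as well. Cytosolic ribosomal protein genes were lower as a list (75 tested, median −0.18, camera adjusted p = 7.94e-04; adjusted p = 0.865 with an estimated correlation), with 1 rising and 5 falling members. RPL9 rose, and the falling members included RPS15 (to 0.665 of WT) and, named after their values were seen, RPS2, RPS14 and RPS26, whose 4 calls were lost with the GC trend removed. Adjusted over the list alone, 1 rose and 7 fell, and 33 of the 75 may share reads.

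Markers of ovarian clear cell carcinoma included rising and falling members. Of 17 tested, 4 rose, CRYAB, the protease inhibitor gene TFPI2 (1.80-fold) and, named after its values were seen, SPP1 among them, and the Na,K-ATPase regulator gene FXYD2, which may share reads, fell to 0.614 of WT. In this list 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.240), and with the GC trend removed the call of CRYAB alone was kept. The log2 changes of TFPI2 and FXYD2 then were 0.62 and −0.65, from 0.85 and −0.70. Of 16 mesenchymal markers, the hyaluronan receptor gene CD44 rose 1.84-fold and SPARC 1.53-fold, 2 also adjusted over the list alone. Of 24 extracellular matrix genes, 2 rose, among them the collagen gene COL1A2 (2.79-fold), and FBLN1 fell to 0.550 of WT, with 3 rising and 1 falling adjusted over the list alone. Camera's adjusted p was 0.204 for mesenchymal and 0.465 for matrix genes, and 0.0411 and 0.0111 with the GC trend removed, but 0.804 for both with an estimated correlation as well. The matrix median, 0.21, lay at the 97.6 percentile of random lists, but was 0.30 with shRNA 1 and −0.05 with shRNA 2. The calls of SPARC and FBLN1 were lost with the GC trend removed, at log2 changes of 0.61 and −0.63, from 0.61 and −0.86. Of 19 epithelial markers, LAD1 fell to 0.663 of WT, a call lost with the GC trend removed, and 1 rose and 1 fell adjusted over the list alone. That list's median was −0.06 and its mean 0.09, with camera's direction down (adjusted p = 0.983).

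Markers of other cell types were low or gave no shift as a list. Leukocyte markers held 76, 70 and 47 counts in WT, shRNA 1 and shRNA 2, and 2 of the 19, CD8A and LYZ, had enough counts to be tested, without passing. Of 6 tested fibroblast and endothelial markers, RGS5, which may share reads, rose 1.59-fold, a call lost with the GC trend removed, 1 also adjusted over the list alone (camera adjusted p = 0.565). Of 25 housekeeping genes, B2M rose 1.55-fold and GAPDH fell, with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.565), and both calls were lost with the GC trend removed.

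**Figure D3:**
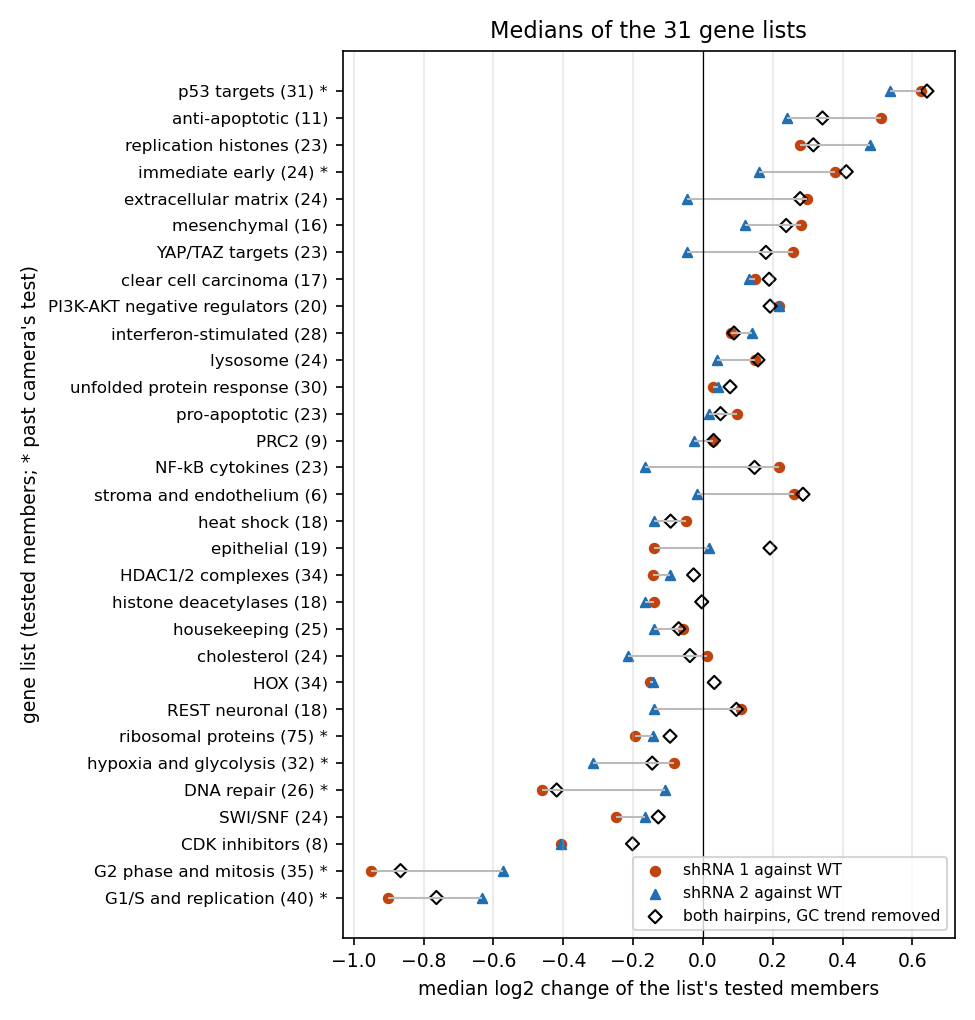
Median log2 change against WT of the tested members of each of 31 gene lists, with circles for shRNA 1, triangles for shRNA 2 and open diamonds for both hairpins with the GC trend removed; an asterisk marks the 7 lists past camera's test with the preset correlation. The p53 target medians lie at 0.63 and 0.54 for the hairpins, and the G2 and mitosis medians at −0.95 and −0.57.

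List medians had one sign in both hairpin libraries for 23 of 31 lists and opposite signs for 8, among them NF-kB cytokines (0.22 with shRNA 1 and −0.17 with shRNA 2), YAP targets (0.26 and −0.04) and cholesterol genes (0.01 and −0.21). The p53 target median was 0.63 with shRNA 1 and 0.54 with shRNA 2, the G2 and mitosis median −0.95 and −0.57, and the G1/S median −0.90 and −0.63. HDAC2 fell by 1.65 and 1.03 and CDKN1A rose by 1.78 and 1.22 on the log2 scale. By size alone, 493 genes changed at least 2-fold with both hairpins in the same direction, 269 upwards and 224 downwards. Both changes were taken against the same WT library, which alone gave 127 such genes on average in 50 simulations of unchanged libraries. Independent lists of the observed lengths would share 15.8 genes upwards and 17.8 downwards.

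Across genes, which are not independent replicates, the log2 changes of the hairpins had a Pearson correlation of 0.707 and a Spearman correlation of 0.736, against simulated values of 0.512 and 0.475. Their covariance was 0.264 against 0.0819 in the simulations, a difference of 0.182, and 79.1% of genes had the same sign against 66.9%. With 1 WT library the control could not be split, so part of the excess may come from the shared library. Of the 493 genes, 278 had no near-identical copy.

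Between the hairpins, 522 genes differed at least 2-fold, 261 in each direction, without a replicate of either hairpin. Unchanged simulated libraries gave 427.6 on average. Their spread came from the main fit, which learned it from these same 2 hairpin libraries. The simulated number therefore already holds differences between hairpins and cannot show how small they are. The genes highest in shRNA 2 by the rule were RPS27P3 (0 and 688 counts with shRNA 1 and shRNA 2), PSMC1P1 (0 and 175) and PALM2AKAP2 (0 and 117). The lowest were SRGAP2C (ENSG00000236933; 80 and 0 counts), TECRP1 (89 and 2) and UPK3BL1 (75 and 3). All 6 may share reads with another gene. With a mean count of at least 50, 68 genes differed.

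Changes followed the GC content of the transcripts. The median log2 change was 0.32 for the 1828 genes under 40% GC and −0.30 for the 1098 genes over 60%. Over 10035 well-expressed genes the Spearman correlation with GC content was −0.567, and it was −0.453 with shRNA 1 and −0.623 with shRNA 2. The hairpin libraries differed from each other in the same direction, with a correlation of −0.341. Transcript length had a correlation of 0.233 with the change.

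**Figure D4:**
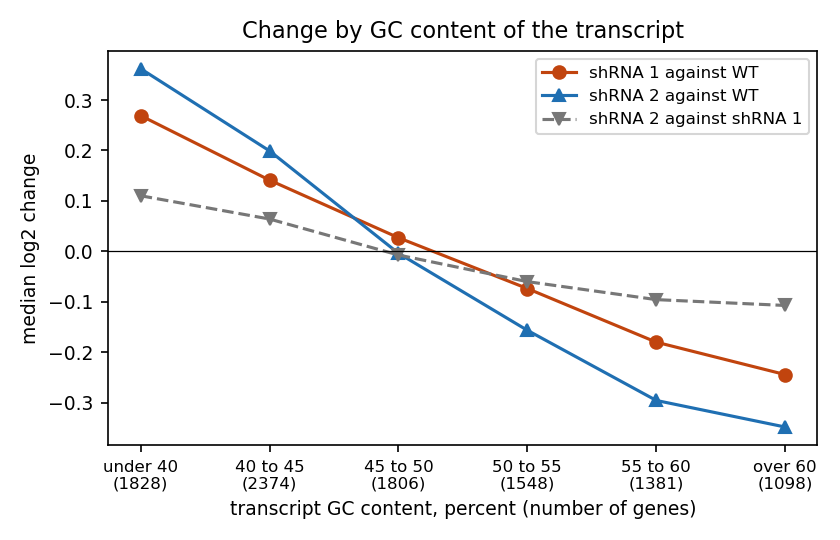
Median log2 change (y axis) of tested genes in 6 bins of transcript GC content (x axis, percent, with the number of genes), for shRNA 1 against WT, shRNA 2 against WT, and shRNA 2 against shRNA 1. The medians fall from 0.27 and 0.36 in the lowest bin to −0.24 and −0.35 in the highest.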

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

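The test of read sharing described here was chosen only after the result was seen. In 3 named genes with at least 50 counts in a library, the hairpins moved at least 2-fold in opposite directions from WT, a difference between hairpins that was not tested, since each hairpin has 1 library. The row of the pseudogene RPS27P3 held 114 counts in WT, 0 with shRNA 1 and 688 with shRNA 2, which is at least 232-fold higher with shRNA 2 than with shRNA 1 against a floor of 3 counts per library. PALM2AKAP2 held 20, 0 and 117 counts, at least 39.5-fold higher with shRNA 2. BOP1 (ENSG00000204775) held 33, 105 and 15 counts, 6.91-fold higher with shRNA 1. All 3 share sequence with another gene or stand under a repeated or unlisted ID, and this held for 9 of the 10 genes with such opposite changes at any count.

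The largest fold changes between knockdown and WT lay mostly in genes that may share reads with others. Of 67 genes past the test with at least a 4-fold change, 58 (86.6%) may share reads, against 199 of 1054 (18.9%) with smaller changes (Fisher's exact test over genes, two-sided, p = 2.26e-30, odds ratio 27.6). These counts include IDs with no sequence in the reference, whose sharing was not measured. Genes that are copies of each other are also not independent in that test. A candidate explanation is that reads were assigned to different near-identical copies in different libraries. When genes that share at least 50% of their sequences were summed, 7 of the 40 such calls of at least 4-fold in summed groups (17.5%) still passed, against 112 of 157 (71.3%) calls of smaller size. Summing a row of few counts with copies of more counts tends to shrink its change, whatever the cause. The contrast therefore cannot by itself tell misassigned reads from other causes. A real shift from 1 copy to another was not tested, and stays open for each gene, as does a biological difference between WT and knockdown cells.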

How the results depend on the processing

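No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. HDAC2 was lower under all 10 alternatives, at log2 changes of −1.03 and −1.65 with a hairpin left out, values with no test. Its adjusted p ranged from 2.48e-11 to 0.468 over 8 alternatives, and it missed the threshold in 1 of them, with no filter on low counts (−1.31). The count of 1121 changed genes became 0 with no filter (edgeR, 2486 at an unadjusted p below 0.05; 306 by DESeq2's Wald test on the filtered table). That fit had a prior of 1.92 degrees of freedom against 18.9. The count was 306 with DESeq2's Wald test, 391 at an adjusted p below 0.01 and 1866 below 0.1. With the GC trend removed it was 492, in a fit with a prior of 11.5 degrees of freedom. It stayed within 1.5 times the main count with DESeq2 size factors (1019), library size alone (1463), upper quartile scaling (1023), a mean count of at least 50 (937), the likelihood ratio test (1252), limma-voom (1058), without mitochondrial copies, histones and small RNAs (1136), with genes that share sequence summed (1670) and among genes with no near-identical copy (831).

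The 493 genes changed at least 2-fold by both hairpins became 1087 with no filter, 173 at a mean count of at least 50, 260 with a prior count of 8, 278 among genes with no near-identical copy, 1796 at 1.5-fold and 63 at 4-fold; a single hairpin gave 960 to 1016. The correlation between hairpins was 0.784 at a mean count of at least 50. Of the 522 genes differing between hairpins, 68 did at that count and 83 at 4-fold. The 7 list calls became 0 with an estimated correlation. No list passed that test, which ran on 1 residual degree of freedom and cannot weigh single calls. Of the list medians, 12 lay outside the central 95% of random lists. The GC trend and the sequence-sharing alternatives were chosen after seeing the data. Apart from the fewer or more genes that a filter, threshold or fit lets through, the cause was not tested.

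Summing genes that share sequence reversed 2 named changes, to −0.19 for UBE2F-SCLY and 0.055 for TMSB4XP6, each being the value of a summed group. Over 138 named genes and their alternatives, 1049 values kept direction and side of the threshold, 241 fell short of it (105 with no filter, 68 with DESeq2's Wald test and 42 with the GC trend removed), 13 newly passed, and 50 moved in size with a hairpin left out. Over 31 lists, 110 values kept both, 8 fell short (7 of them with an estimated correlation) and 5 newly passed. At this depth genes such as PIK3IP1, with 25 counts in WT, have wide errors.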

Other observations

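The genes of this and the next paragraph were chosen after their values were seen, among protein-coding genes with no near-identical copy and a few noncoding RNAs. They are single genes picked by hand, with no test of them as a group. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ESPL1, the protease separase, fell to 0.347 of WT (599 counts in WT, 225 and 250 with the hairpins), FOXM1, a transcription factor of mitotic genes, to 0.423, DBF4B, an activator of the kinase CDC7, to 0.374, and TONSL, a replication repair protein, to 0.362. TERT, the catalytic subunit of telomerase, had 25 counts in WT and 2 and 3 with the hairpins, and passed (adjusted p = 0.0119), but not with the GC trend removed (adjusted p = 0.0595). Its log2 change was −3.45 in the main fit and −3.08 with the trend removed.

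Other genes rose in both hairpin libraries by the same test. NEAT1, a nuclear long noncoding RNA of paraspeckles, rose 2.22-fold beside MALAT1, KLHL24, a ubiquitin ligase adaptor, 2.65-fold, RALGPS1, an exchange factor for the GTPase Ral, 3.16-fold and NDUFA5, a subunit of respiratory complex I, 2.82-fold. The complement gene C3 had 1115 counts in WT, 3028 with shRNA 1 and 1116 with shRNA 2, and the growth factor gene HBEGF 84, 116 and 36. Neither hairpin has a replicate, so these differences were not tested.

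Camera's test of the interferon list was planned, and the other tests weighed in the next paragraphs were chosen only after the result was seen. The first pattern is that p53 targets rose while G2/M and G1/S genes fell. GC content bias is argued against as the whole cause, because 55 of the 62 calls in the lists' directions passed again with the GC trend removed, and the medians then were 0.64, −0.87 and −0.76. An off-target effect of 1 hairpin as the whole cause would leave the other hairpin's library unshifted. The 3 medians lay outside the central 95% of random lists in both hairpins' libraries. The nearest to 0 was 0.535 for p53 targets with shRNA 2 (random lists −0.17 to 0.19). Random lists hold genes that need not move together, and the G2 and mitosis median also differed between the hairpins (−0.95 and −0.57). Both libraries were also set against 1 WT library, so these values do not decide on an off-target effect. Viral transduction or the state of the one WT culture cannot be told apart from HDAC2 loss here, since both hairpins were set against 1 WT library with no stated control virus, and the interferon list's camera adjusted p of 0.743 does not decide it. A response of these cells to HDAC2 loss may also be at work, a hypothesis that replicated control-virus libraries and a rescue with hairpin-resistant HDAC2 would test.

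The second pattern is that genes of low GC content rose and genes of high GC content fell. GC bias between libraries is a candidate explanation, since the hairpin libraries also differed from each other along GC content, with a Spearman correlation of −0.341 across genes. Loss of HDAC2 as the source cannot be told apart from it with 1 library per hairpin. The correlation with GC content was −0.453 in the library with less HDAC2 and −0.623 in the other.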
